A study of Mus musculus with 32 samples.

How the data were processed

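Gene expression was measured in 32 samples of mouse brain tissue, 22 gliomas and 10 normal controls, on Affymetrix mouse genome arrays hybridised with biotin-labelled complementary RNA made from total RNA, per the labels. The labels give each array a genotype and a title that names a set, Z1 or Z2, a tissue and a replicate number, and arrays were grouped by these. This gave 6 groups: 9 gliomas from hGFAP-cre;p53KO/+;Nf1+/flox mice, here called cis p53/Nf1 gliomas, with 3 forebrains in set Z1, and 9 gliomas from hGFAP-cre;p53flox/flox mice, called p53 gliomas, 4 gliomas from hGFAP-cre;p53flox/flox;Nf1KO/+ mice, called p53 Nf1KO gliomas, 4 forebrains and 3 cerebella in set Z2. The cerebella carry the numbers 1, 2 and 4. What Z1 and Z2 stand for is not stated in the labels.

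The authors deposited normalized log2 values for 18328 probe sets of a custom definition, as an annotated matrix and as the value table of the series. The 2 tables were compared in every cell and their largest absolute difference was 0. How probe intensities were summarised and normalized, and whether both sets were normalized together, is not given in the sources used here. The deposited log2 values show that the sets lie on different scales: array medians ran from 8.48 to 8.57 in Z1 and from 6.90 to 7.06 in Z2. The lowest value of an array lay between 3.95 and 4.35 in Z1 and between 0.985 and 1.84 in Z2, and the standard deviation within an array was 2.01 to 2.12 in Z1 and 2.58 to 2.66 in Z2. Each glioma model was therefore compared with forebrain of its own set, and models of different sets only through the difference of their differences from forebrain, which removes an additive shift between sets but not a difference in the spread of values.

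Gene names came from the gene identifiers in the deposited matrix, looked up in a reference table of assembly GRCm38.p6, which was used for names, chromosomes and the order of neighbouring genes, with no coordinates printed. In the file 16882 probe sets carried 1 gene identifier and 1446 several. In the reference 17226 probe sets matched exactly 1 gene, of which 599 had several identifiers in the file, 785 matched several genes and 317 none, and 4121 symbols were updated. The named probe sets covered 16195 genes. For each gene the probe set with the highest mean over the 32 arrays was kept, and unnamed probe sets stayed as they were, which left 17240 features, called genes here. No filter on low values was applied in the main setting.

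A model with 1 mean per group was fitted to all 32 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), so that the 6 groups share 1 estimate of the spread. The 8 contrasts were each glioma model against forebrain of its set, p53 Nf1KO against p53 gliomas, the cis p53/Nf1 gliomas against each of the other models with every group taken relative to its own forebrain, cerebellum against Z2 forebrain, and Z1 against Z2 forebrain. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and the number that also differed at least 2-fold was counted. Log2 differences are printed with the standard error of the fit. Tests are two-sided. Nf1, Trp53 and Rictor were also tested alone by an exact permutation test of the difference in means within a set, with adjustment over the 15 such tests.

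Of 32 gene lists, each was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 32 lists of a contrast, and again with a correlation estimated from the data and with fry. The lists were targeted and mTOR complex genes, PI3K-AKT-mTOR signalling, receptor tyrosine kinases and ligands, RAS-MAPK output, p53 target genes, mitosis, DNA replication, oligodendrocyte progenitor, myelinating oligodendrocyte, astrocyte, neural stem and progenitor, neuroblast and immature neuron, mature neuron, microglia and macrophage, T and NK cell, granulocyte, endothelial, pericyte and fibroblast, extracellular matrix, interferon response, MHC class II presentation, hypoxia and glycolysis, SHH pathway, mesenchymal glioma, proneural glioma, forebrain regional, cerebellum regional, choroid plexus and ependyma, erythrocyte, immediate early, PRC2 and chromatin, and sterol synthesis. All measured members entered the tests; the shortest list was erythrocyte, with 4 of 11 genes measured. Some genes stand in more than 1 list. The genes of each of 20 chromosomes were tested in the same way in 5 contrasts. Shared calls were counted between models with separate controls, beside the number that independent lists would share.

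The groups, contrasts, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule took, per contrast, the 10 genes with the largest positive and the 10 with the largest negative difference among called genes whose arrays did not overlap between the groups, leaving out unnamed and provisional gene models. It also took Trp53, Nf1 and Rictor throughout, and up to 4 members of each list with the smallest p together with called members that went against the direction of the others. Some genes that the rule names are not reported here. Genes outside it are said to have been chosen after their values were seen.

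Alternatives were the mean of a gene's probe sets or the one with the largest variance, leaving out the lowest 40% of genes by mean, quantile normalization, median-centring, limma-trend with robust eBayes, array weights, a fit to the compared groups alone, the replicate number as a block, an added 2-fold threshold, an adjusted p under 0.01, all 7 forebrains as 1 group, cerebellum as the reference, a direct difference between glioma groups, and leaving out each array of the groups of 3 or 4. Leaving out p53 glioma 1, and cis p53/Nf1 gliomas 4 and 8 together, was added after the data were seen. The main fit of each comparison was tested on simulated data: with 17240 genes drawn around each gene's mean with its residual spread, changes of 2 on the log2 scale were called for 90.9% of changed genes in the cis p53/Nf1 contrast, 92.4% in the p53 contrast, 95.5% in the p53 Nf1KO contrast, 93.9% between the 2 Z2 models, 75.8% and 72.7% in the differences of differences, and 83.3% between cerebellum and forebrain. In the same order, changes of 1 were called for 62.7%, 67.2%, 53.7%, 50.7%, 37.3%, 32.8% and 41.8%. Changes of 0.5 were called for 16.4%, 22.4%, 13.4%, 20.9%, 4.48%, 5.97% and 2.99%, so many of that size were missed in the simulation. Only 66 or 67 genes were changed at each size, with 120 calls in the cis p53/Nf1 run beside 7266 in the data. Where the data give many more calls, the adjusted p threshold is less strict. These shares may therefore be too low for gliomas against forebrain. The number of arrays limits the precision. The labels do not say that the arrays come from separate animals, so p-values measure the spread between these samples. Figures were drawn with Matplotlib 3.10.9, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Medulloblastomas, which the protocols mention, were not analysed here.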

Results

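The series profiled high-grade gliomas from 3 mouse models that lose the tumour suppressor p53 through a conditional or germline allele, alone or together with a mutation of Nf1, which encodes the RAS-inactivating protein neurofibromin. Normal forebrain and cerebellum served as controls. The series title concerns Rictor, a core subunit of mTOR complex 2, in glioma and SHH medulloblastoma. Set Z1 held 9 cis p53/Nf1 gliomas and 3 forebrains, and set Z2 held 9 p53 gliomas, 4 p53 Nf1KO gliomas, 4 forebrains and 3 cerebella. No 2 arrays of a group held identical values. The median difference between replicates (root mean square, log2) was 0.380 in Z1 forebrain, 0.503 in Z2 forebrain, 0.598 in cis p53/Nf1 gliomas, 0.771 in p53 gliomas and 0.742 in p53 Nf1KO gliomas.

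The genes targeted in the models were examined first, in every array. Nf1, on chromosome 11, read 5.55 ± 0.20 (SD, n = 4; 5.26 to 5.70) in p53 Nf1KO gliomas, below all arrays of p53 glioma (6.33 ± 0.35, SD, n = 9; 5.92 to 6.83) and of Z2 forebrain (6.19 ± 0.01, SD, n = 4). Against p53 gliomas this was a difference of -0.78 ± 0.16 (limma adjusted p = 0.0354; exact p = 0.0042, adjusted over 15 tests 0.0629), and against forebrain -0.64 ± 0.18 (limma adjusted p = 0.0279; exact p = 0.0286, adjusted 0.107). With 4 gliomas against 4 forebrains, also for Trp53 below, 0.0286 is the smallest p that the exact test can give. The limma call against p53 gliomas is lost with quantile normalization (-0.71), a fit to the compared groups alone (-0.78), an adjusted p under 0.01, and without p53 Nf1KO glioma 1 (-0.68) or 2 (-0.80). The call against forebrain is lost at an adjusted p under 0.01, without any 1 of the 4 Z2 forebrains (-0.64 or -0.65), and without p53 Nf1KO glioma 1 (-0.55) or 4 (-0.70). In the cis p53/Nf1 gliomas, which carry 1 conditional Nf1 allele, Nf1 read 7.98 ± 0.27 (SD, n = 9) beside 7.90 ± 0.16 (SD, n = 3) in Z1 forebrain, with limma adjusted p = 0.785 and exact p = 0.723. Trp53, also on chromosome 11, read 5.30 ± 0.20 (SD, n = 4) in p53 Nf1KO gliomas, 5.79 ± 0.38 (SD, n = 9) in p53 gliomas and 6.07 ± 0.36 (SD, n = 4) in Z2 forebrain. It differed from forebrain in p53 Nf1KO gliomas by -0.77 ± 0.22 (limma adjusted p = 0.031; exact p = 0.0286, adjusted over 15 tests 0.107). This call is lost in a fit to the compared groups alone, at an adjusted p under 0.01, without Z2 forebrain 2 (-0.62) or 3 (-0.73), and without p53 Nf1KO glioma 1 (-0.75), 2 (-0.69) or 4 (-0.84). For Trp53 the differences of -0.29 in p53 gliomas and -0.34 in cis p53/Nf1 gliomas were not called (limma adjusted p = 0.242 and 0.211). Rictor, on chromosome 15, was called in none of the 7 comparisons of tissue or model; its difference from forebrain was 0.12 ± 0.18 in cis p53/Nf1, -0.04 ± 0.16 in p53 and -0.18 ± 0.19 in p53 Nf1KO gliomas (limma adjusted p = 0.63, 0.855 and 0.553). Where the probes lie relative to the deleted parts of Trp53 and Nf1 is unknown, so a level near that of forebrain checks nothing about the alleles.

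**Figure D1:**
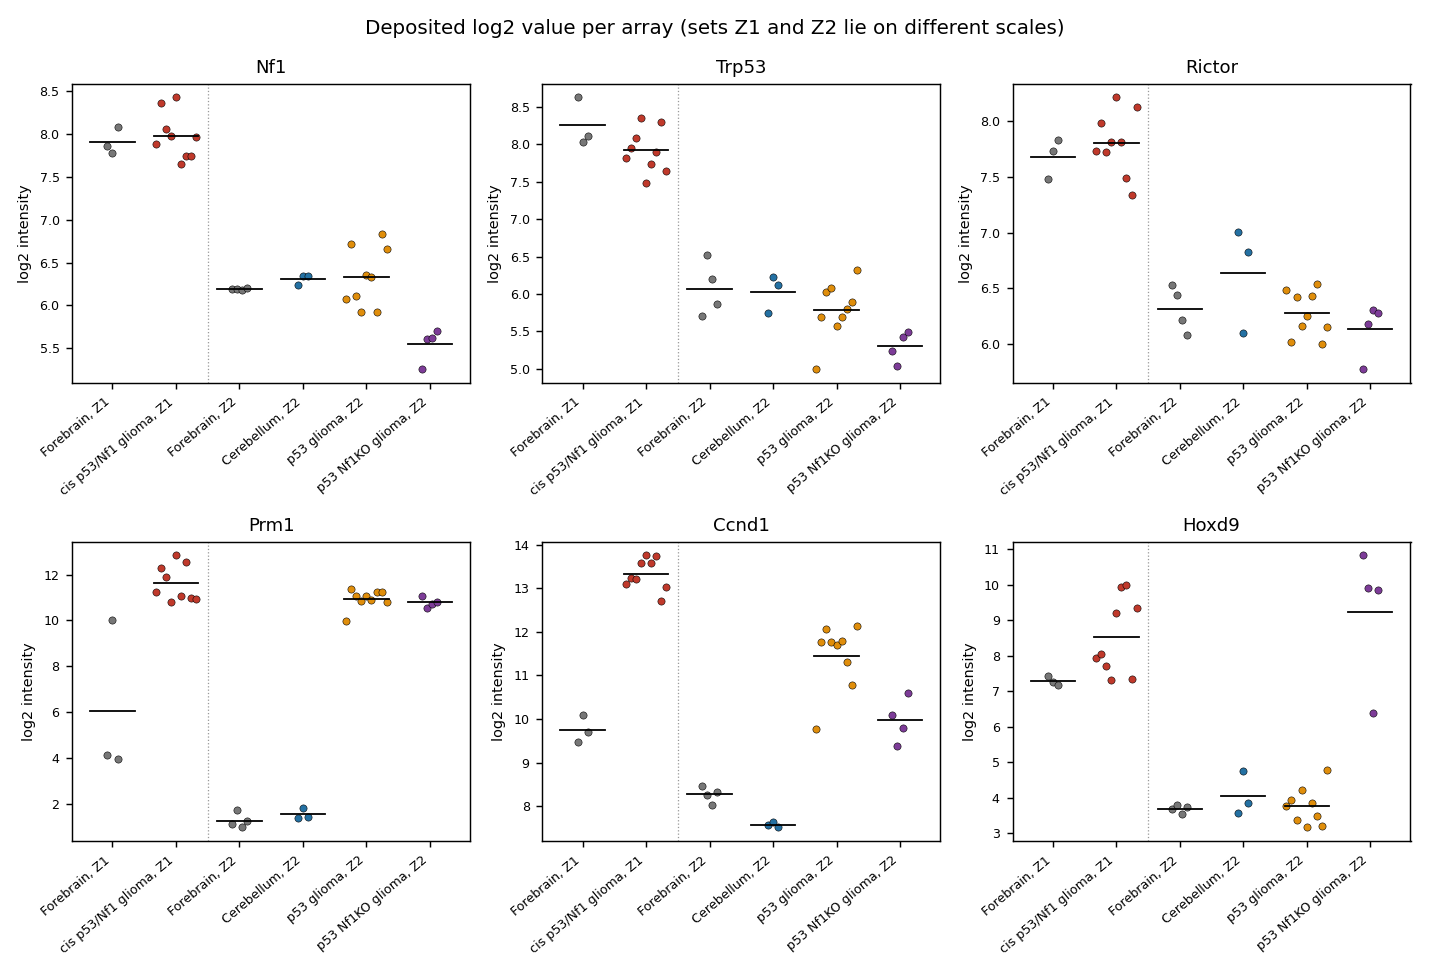
Deposited log2 value of 6 genes on each of the 32 arrays by group; each point is 1 array, the horizontal line is the group mean, and the dotted line parts sets Z1 and Z2, which lie on different scales. Nf1 in the 4 p53 Nf1KO gliomas lies between 5.26 and 5.70, below every p53 glioma (5.92 to 6.83).

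Cis p53/Nf1 gliomas were compared with forebrain of their set to find what distinguishes these tumours from normal tissue. Cell division genes were among those with the largest rise: the proliferation marker Mki67 stood at 11.44 ± 0.69 (SD, n = 9) beside 5.72 ± 0.13 (SD, n = 3), 52.7-fold higher, and Top2a, the topoisomerase that untangles replicated DNA, was 52.2-fold higher. Rrm2, a subunit of ribonucleotide reductase, rose by 5.61 ± 0.58, Nusap1 by 5.36 ± 0.60, Bub1 by 5.28 ± 0.73, Ect2 by 5.23 ± 0.58 and Cdc20, an activator of the anaphase-promoting complex, by 5.23 ± 0.65. A second Rrm2 probe set read 3.07, also called. Neuronal genes led the lower ones: Kalrn, an exchange factor of dendritic spines, was 93.1-fold lower (6.25 ± 0.81 beside 12.79 ± 0.18, SD), the neuropeptide Cck 68.1-fold, the calcium sensor Vsnl1 62.6-fold, the AMPA receptor subunit Gria1 52.1-fold and neurofilament light chain Nefl 50.2-fold lower. Mal2, Hpcal4, Car10, Elmod1 and Lamp5 completed the 10, with differences of -6.32, -5.91, -5.73, -5.71 and -5.69. Each of these 17 genes had a limma adjusted p of 9.44e-05 or less. In all, 3766 genes were higher and 3500 lower of 17240, and 3828 of the 7266 changed at least 2-fold. With median-centred arrays the higher share was 48.6% in place of 51.8%. Of the genes, 3077 were higher and 3071 lower without overlap between the groups, where chance gives 0.909%.

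The remaining higher genes were Nxf3, Prm1 and Haus5. Nxf3, an X-linked member of the nuclear RNA export family, was higher by 6.43 ± 1.31 (limma adjusted p = 0.000228), with cis p53/Nf1 glioma 8 at 5.85 and the other arrays of the group between 10.28 and 13.29. The protamine gene Prm1, normally a sperm chromatin protein, was higher by 5.58 ± 0.69 (limma adjusted p = 4.66e-07), although Z1 forebrain 2 read 10.01 where the other two read 4.15 and 3.95, the lowest values of their arrays. Haus5, a subunit of the augmin complex of the mitotic spindle, was higher by 5.32 ± 0.92 (limma adjusted p = 3.1e-05) and lies on chromosome 7 close to the genes Arhgap33 to Zbtb32, whose median was 3.17 to 3.88 above forebrain in 7 of the 9 gliomas; these genes were chosen after their values were seen.

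Of the lists fixed beforehand, 16 were called in cis p53/Nf1 gliomas with the preset correlation and none with an estimated one, where the lowest adjusted p was 0.316; fry called 20. For these gliomas, counts adjusted over the list alone are given where they differ from those over all genes. For the other comparisons they are given for some of the lists. All 31 measured mitosis genes rose (median 3.83, adjusted p = 1.48e-17, and adjusted p = 0.355 with an estimated correlation). So did 27 of 29 DNA replication genes, among them Rfc3 (2.74 ± 0.32) and Mcm4 (2.66 ± 0.31), with a median of 2.47 and adjusted p = 2.1e-13 (adjusted p = 0.359 with an estimated correlation). Of 17 oligodendrocyte progenitor genes 16 rose, 17 when adjusted over the list alone (median 2.81, adjusted p = 8.28e-09; adjusted p = 0.316 with an estimated correlation). They include the transcription factors Nkx2-2 (3.62 ± 0.45) and Olig2 (3.37 ± 0.42) and the receptor Pdgfra (2.90 ± 0.55; glioma 8 lay 0.03 below forebrain in log2, at 9.75). Stem and progenitor genes rose for 13 of 21 (14 higher and 1 lower adjusted over the list alone), with Vim 22.7-fold, Fabp7 by 2.48 ± 0.22 and Sox2 by 1.51 ± 0.17 (adjusted p = 7.13e-05; adjusted p = 0.316 with an estimated correlation). The interferon response list had 22 of 25 members higher, among them the deubiquitinase-like Usp18 (4.97 ± 0.60) and Irf9 (2.70 ± 0.34; adjusted p = 3.85e-09; adjusted p = 0.384 with an estimated correlation).

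All 34 mature neuron genes fell in the cis p53/Nf1 gliomas (median -3.65, adjusted p = 1.34e-17; adjusted p = 0.316 with an estimated correlation), including the synaptic genes Snap25 (-4.08 ± 0.43), Syn1 (-3.08 ± 0.36) and Dlg4 (-2.90 ± 0.31). Forebrain regional genes fell for 19 of 25, 21 adjusted over the list alone, with the cortical factors Tbr1 (-4.32 ± 0.91) and Bcl11b (-3.40 ± 0.50; adjusted p = 2.1e-06; adjusted p = 0.355 with an estimated correlation). Normal glia were lower too: 13 of 20 myelinating oligodendrocyte genes fell, such as Mog (-3.92 ± 0.56) and Mbp (-2.69 ± 0.40), and 13 of 19 astrocyte genes, such as the gap junction gene Gja1 (-4.11 ± 0.62) and Glul (-1.18 ± 0.22). The adjusted p-values for these were 7.13e-05 and 0.000903, with adjusted p = 0.384 and adjusted p = 0.431 with an estimated correlation. Sterol synthesis genes fell for 9 of 20, 10 adjusted over the list alone, with Msmo1 at -2.01 ± 0.36 and Sc5d at -1.50 ± 0.28 (adjusted p = 0.00161; adjusted p = 0.468 with an estimated correlation).

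Tumour, myeloid, matrix and chromatin lists were called higher, most of them with some members lower. In the RAS-MAPK output list 10 of 18 genes rose, with Myc by 3.99 ± 0.46, Ccnd1 by 3.58 ± 0.33 and Etv4 by 3.33 ± 0.49, while the ephrin receptor Epha4 fell by 3.18 ± 0.45 (adjusted p = 0.00241; adjusted p = 0.384 with an estimated correlation). Proneural glioma genes were higher for 16 of 24 (18 adjusted over the list alone), with Sox4 at 2.77 ± 0.30, and lower for Stmn1, Rab33a and Gsk3b, at -1.39, -1.92 and -0.70 (adjusted p = 7.13e-05; adjusted p = 0.316 with an estimated correlation). The mesenchymal glioma list had 17 of 24 higher (18 adjusted over the list alone), with Lgals3 at 4.56 ± 0.63 and Stat3 at 1.86 ± 0.27, and 2 lower, Bhlhe40 and Chil1 (adjusted p = 7.13e-05; adjusted p = 0.384 with an estimated correlation). Microglia and macrophage genes were higher for 11 of 28, 12 adjusted over the list alone, with lysozyme Lyz2 at 3.72 ± 0.60 and Cd68 at 1.66 ± 0.34. The microglial purinergic receptors P2ry12 (-1.87 ± 0.50) and P2ry13 (-0.91 ± 0.37) were lower (adjusted p = 0.00751; adjusted p = 0.648 with an estimated correlation). Extracellular matrix genes rose for 12 of 26, with Vcan at 3.46 ± 0.57 and Lama4 at 2.52 ± 0.44 (adjusted p = 0.00104; adjusted p = 0.581 with an estimated correlation). In the PRC2 and chromatin list 9 of 15 rose, 10 adjusted over the list alone, with the methyltransferase Ezh2 at 4.06 ± 0.52, while Ezh1 fell by 1.82 ± 0.25 (adjusted p = 0.00272; adjusted p = 0.384 with an estimated correlation).

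The other 16 lists were not called by camera in cis p53/Nf1 gliomas. Of these, fry called MHC class II higher (fry adjusted p = 0.0304). It called hypoxia and glycolysis (0.0309), cerebellum regional (0.0227) and erythrocyte genes (0.0226) lower. Among the targeted and mTOR complex genes 2 were higher and 2 lower of 13, with Akt1s1 at 0.73 ± 0.20, the mTOR inhibitor Deptor at -2.67 ± 0.37 and Mtor at -0.85 ± 0.16; a second Mtor probe set read 0.15, uncalled. PI3K-AKT-mTOR signalling had 5 higher and 4 lower of 24, with the translation repressor Eif4ebp1 at 3.26 ± 0.43 and Pdpk1 at -1.13 ± 0.17. Receptor tyrosine kinases and ligands had 5 higher, such as Axl (1.23 ± 0.28), and 4 lower of 29. The p53 target genes had 8 higher, such as Trp53inp1 (1.25 ± 0.25), and 7 lower, such as Ccng1 (-1.08 ± 0.15), of 28. Higher and lower members numbered 3 and 6 of 15 neuroblast, 1 and 1 of 19 T and NK cell (0 adjusted over the list alone), 0 of 13 granulocyte, 3 and 5 of 22 endothelial (5 and 6 adjusted over the list alone). They numbered 2 and 3 of 18 pericyte and fibroblast (2 and 2 adjusted over the list alone), 2 and 0 of 10 MHC class II, 3 and 8 of 23 hypoxia and glycolysis (3 and 9 adjusted over the list alone), and 3 and 3 of 17 SHH pathway genes. Counts were 2 and 8 of 27 cerebellum regional, 0 and 3 of 16 choroid plexus and ependyma, 0 and 1 of 4 erythrocyte and 2 and 4 of 19 immediate early genes. Median, mean and test differed in sign for the targeted and the T and NK cell lists.

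**Figure D2:**
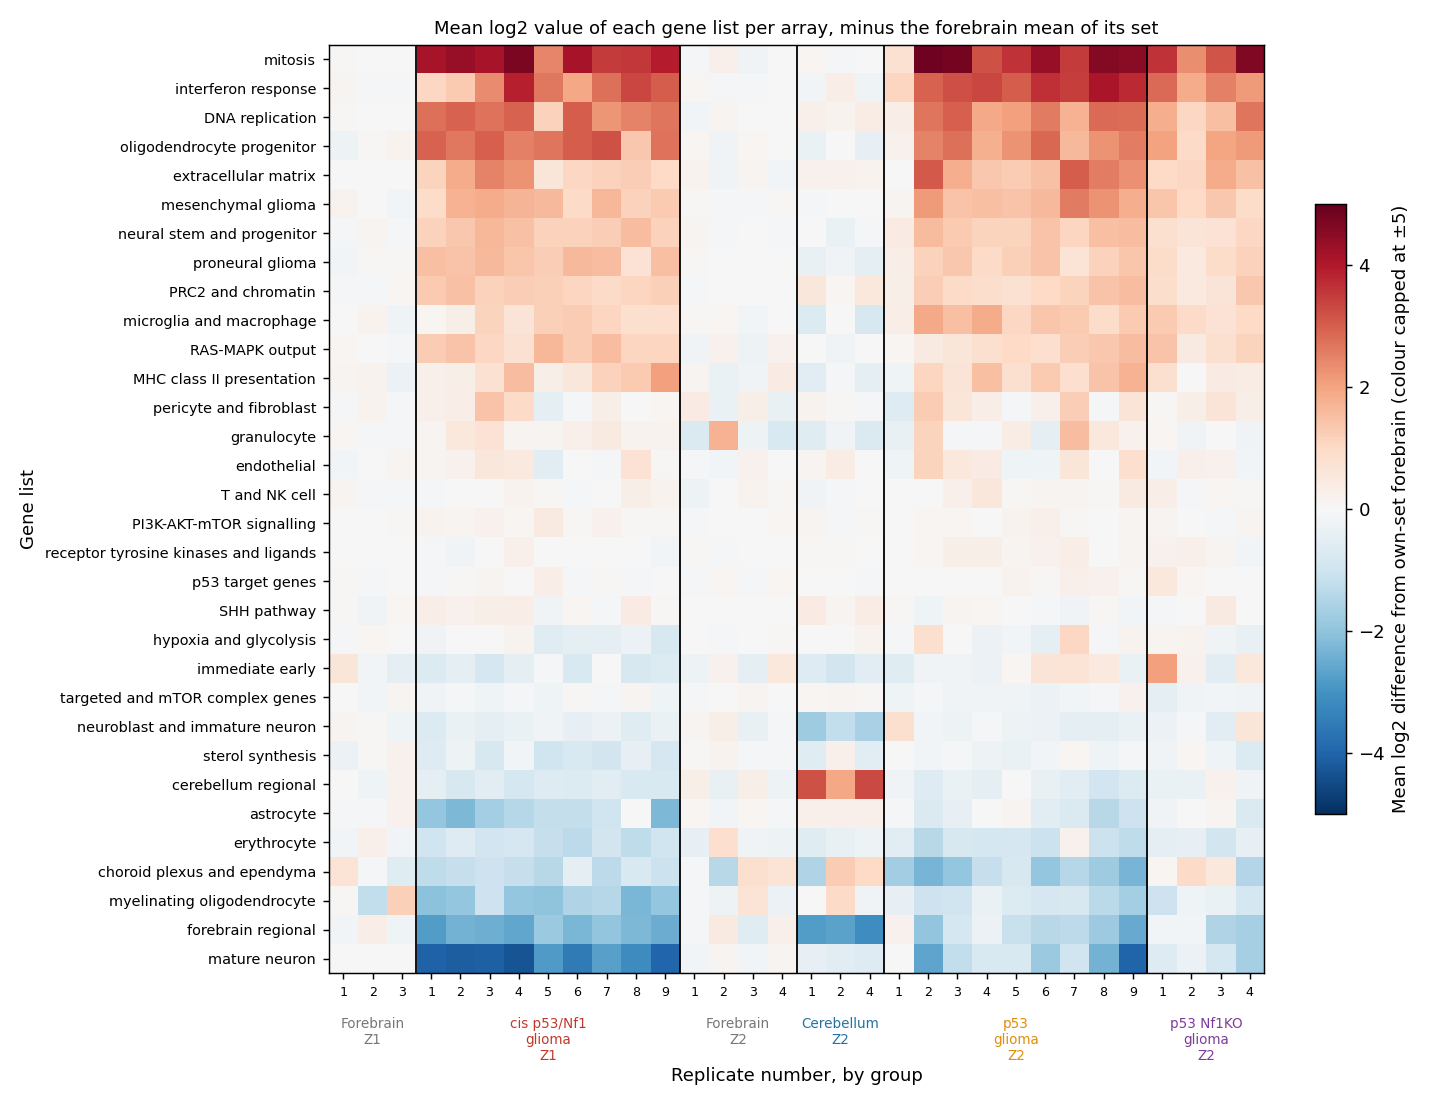
Mean log2 value of the members of the 32 gene lists on each array minus the mean of the forebrain arrays of the same set; columns are arrays by group and replicate number, and colour is capped at 5 either way. The mitosis list reads 0.74 in p53 glioma 1 and 2.31 or more in the other gliomas.

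The p53 gliomas were compared with forebrain of set Z2. Prm1 stood at 10.94 ± 0.41 (SD, n = 9) beside 1.28 ± 0.33 (SD, n = 4), a difference of 9.66 ± 0.63. Its forebrain readings (0.99 to 1.75) lie at or next to the lowest value of each array, so they are not above background and the size of the difference is set by that floor. Of the other 9 leading genes, those in the mitosis list were the cyclin Ccnb1 (66.4-fold higher), Cdk1 (42.3-fold), Nusap1 (37.6-fold) and Ect2 (37.1-fold). Outside that list were the interferon-induced chemokine Cxcl10 (57.8-fold), the mitotic kinase Pbk (52.0-fold), the PCNA-associated Pclaf (46.7-fold), the cohesin acetyltransferase Esco2 (45.0-fold) and Cdca3 (43.5-fold). A second Pclaf probe set read -0.37, uncalled. Among genes without overlap between the groups, p53 glioma 1 included, the lower ones changed less. The orphan receptor Gpr12 was 8.52-fold lower, the gastrokine Gkn3 8.41-fold and the fatty acid transporter Slc27a2 8.23-fold. Unc13c, a factor of synaptic vesicle priming, and the cadherin Cdh8 were each 6.97-fold lower. Lemd1, Pcsk1, Sptssb, Slc6a20a and St6galnac5 followed at -2.80, -2.79, -2.76, -2.69 and -2.69. Called genes numbered 6599, 3044 higher and 3555 lower (limma). Of these, 2865 changed at least 2-fold, 1456 higher and 1409 lower. With median-centred arrays the higher share was 38.6% in place of 46.1%. Without overlap between groups 898 were higher and 792 lower, where chance gives 0.28%. All but 1 of the p53 gliomas lay 74.6% to 140.1% along the mean change from forebrain; p53 glioma 1 lay at 14.2%.

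In p53 gliomas 16 lists were called, none with an estimated correlation (lowest adjusted p = 0.139 with an estimated correlation), and fry called 18. All 31 mitosis genes (median 3.82, adjusted p = 8.62e-27; adjusted p = 0.157 with an estimated correlation) rose. DNA replication genes rose for 27 of 29, with Tk1 at 4.71 ± 0.57 and Pole at 3.77 ± 0.49 (adjusted p = 4.54e-17; adjusted p = 0.219 with an estimated correlation). All 25 interferon response genes rose, with a median of 3.22, among them Usp18 (5.19 ± 0.54), Oasl2 (4.79 ± 0.58) and Mx1 (3.23 ± 0.35; adjusted p = 1.01e-20; adjusted p = 0.157 with an estimated correlation). All 17 oligodendrocyte progenitor genes rose, with Nkx2-2 at 2.42 ± 0.40, Olig2 at 2.34 ± 0.38 and Pdgfra at 2.29 ± 0.49 (adjusted p = 7.28e-10; adjusted p = 0.157 with an estimated correlation). Stem and progenitor genes rose for 10 of 21 (11 adjusted over the list alone), with Fabp7 at 2.08 ± 0.20, and proneural genes for 14 of 24 (16 adjusted over the list alone), with Sox4 at 2.48 ± 0.27. Adjusted p came to 2.31e-07 and 6.83e-06, with adjusted p = 0.139 and adjusted p = 0.157 with an estimated correlation. Mesenchymal genes rose for 19 of 24 (20 adjusted over the list alone), with Lgals3 at 4.17 ± 0.57 and S100a4 at 3.21 ± 0.47. Matrix genes rose for 18 of 26 (19 adjusted over the list alone), with tenascin Tnc at 4.07 ± 0.80 and Vcan at 3.54 ± 0.51. These lists had adjusted p-values of 5.54e-10 and 2.73e-08, with adjusted p = 0.157 and adjusted p = 0.25 with an estimated correlation.

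Myeloid genes rose in p53 gliomas, with 19 of 28 microglia and macrophage members higher (22 adjusted over the list alone), such as Gpnmb (4.27 ± 0.65), Cd68 (1.78 ± 0.31) and complement C1qa (1.77 ± 0.31). So did 5 of 10 MHC class II genes, such as H2-Ab1 (1.76 ± 0.52). Adjusted p was 1.06e-08 and 0.00201, with adjusted p = 0.25 and adjusted p = 0.335 with an estimated correlation. RAS-MAPK output genes rose for 7 of 18 (8 adjusted over the list alone), with Ccnd1 at 3.18 ± 0.30, Myc at 3.14 ± 0.42 and the RAS pathway inhibitor Spry1 at 2.57 ± 0.50. Epha4 fell by 1.51 ± 0.40 (adjusted p = 0.00281; adjusted p = 0.335 with an estimated correlation). Chromatin genes rose for 8 of 15, with Hmga2 at 4.36 ± 0.79 and Ezh2 at 3.49 ± 0.47, and Ezh1 fell by 1.12 ± 0.23 (adjusted p = 0.000696; adjusted p = 0.247 with an estimated correlation). Mature neuron genes fell for 28 of 34 (29 adjusted over the list alone; median -1.71), with Grin1 at -1.95 ± 0.38 and Dlg4 at -1.67 ± 0.28. Forebrain regional genes fell for 11 of 25, with Rasgrp2 at -1.63 ± 0.37, and myelin genes for 8 of 20, with Ermn at -2.55 ± 0.59 and Mal at -2.25 ± 0.60. For these lists adjusted p was 2e-08, 0.00094 and 0.0155, with adjusted p = 0.354, adjusted p = 0.354 and adjusted p = 0.615 with an estimated correlation. Choroid plexus and ependyma genes fell for 10 of 16 (11 adjusted over the list alone; median -1.66), with Kl at -2.98 ± 0.78, Clic6 at -2.56 ± 0.64 and Slc13a4 at -2.41 ± 0.47 (adjusted p = 0.000889; adjusted p = 0.354 with an estimated correlation).

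The other 16 lists were not called by camera in p53 gliomas. Of these, fry called cerebellum regional (fry adjusted p = 0.03) and erythrocyte genes (fry adjusted p = 0.00109) lower. Astrocyte genes were lower for 2 of 19 (1 adjusted over the list alone). The targeted list had Deptor at -1.68 ± 0.33 and Mtor at -0.57 ± 0.14 lower, while a second Mtor probe set was called higher (0.46, limma adjusted p = 0.0397), and the PI3K list had 3 higher, such as Eif4ebp1 at 2.88 ± 0.39, and 4 lower of 24 (3 and 3 adjusted over the list alone). Of 19 T and NK cell genes 1 was higher, the chemokine Ccl5 (4.73 ± 0.74), and 2 lower (1 and 1 adjusted over the list alone). Granulocyte genes numbered 3 higher, such as Lcn2 (5.08 ± 0.83), and 3 lower of 13. The cerebellum regional list had 1 higher, the hindbrain gene Hoxa2 (3.26 ± 0.79), and 10 lower of 27, such as Gdf10 (-2.17 ± 0.51). Signs of median, mean and test differed for the neuroblast, T and NK cell, granulocyte, and hypoxia and glycolysis lists.

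The p53 Nf1KO gliomas, against the same 4 forebrains, were compared in a smaller sample. P53 Nf1KO glioma 2 lay 47.9% along the mean change of its group from forebrain, and the other 3 lay at 75.02% to 117%. Prm1 was 9.51 ± 0.74 higher, against the same floor values, Nxf3 7.26 ± 1.39, Ccnb1 5.69 ± 0.68 and the homeobox gene Hoxd9 5.56 ± 0.65 (9.25 ± 1.96, SD, beside 3.69 ± 0.11, SD, n = 4 each). The kinase Pbk was 38.9-fold higher, Pclaf 35.9-fold (second probe set -0.37, uncalled), Cdk1 35.8-fold, Ect2 28.2-fold and the imprinted transcript H19 27.9-fold. Lower genes included the serotonin transporter Slc6a4 (-2.56 ± 0.64), Gkn3 (-2.45 ± 0.37), Ankub1 (-1.90 ± 0.39), Stbd1 (-1.87 ± 0.41) and Paqr7 (-1.83 ± 0.47), then Lrrc49, Them6, Pnmal1, Hddc3 and Hspa12a between -1.78 and -1.68. Called genes numbered 1427, with 904 higher and 523 lower and 807 changed at least 2-fold (limma). With median-centred arrays the higher share was 53.1% in place of 63.3%. The count moved to 412, 621 or 2503 without p53 Nf1KO glioma 4, 1 or 2, to 930, 783, 895 or 791 without forebrain 1, 2, 3 or 4, and to 2248 without p53 glioma 1, which enters through the shared spread. Without overlap 1739 genes were higher and 1808 lower, where chance gives 2.86%.

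In p53 Nf1KO gliomas 14 lists were called, none with an estimated correlation (lowest adjusted p = 0.108 with an estimated correlation). Fry called 13, among them 2 lists that camera did not call. These were targeted and mTOR complex genes (fry adjusted p = 0.0211) and erythrocyte genes (fry adjusted p = 0.036), both lower. In the targeted list 0 were higher and 2 lower of 13 (3 lower adjusted over the list alone). All 31 mitosis genes rose (median 3.22, adjusted p = 1.23e-38; adjusted p = 0.108 with an estimated correlation). So did 20 of 29 DNA replication genes (23 adjusted over the list alone), with Tk1 at 4.21 ± 0.67 and Mcm6 at 3.74 ± 0.71 (adjusted p = 1.38e-18; adjusted p = 0.158 with an estimated correlation). Interferon genes rose for 22 of 25, with Oasl2 at 4.04 ± 0.68 and Usp18 at 4.03 ± 0.64, and oligodendrocyte progenitor genes for 11 of 17 (15 adjusted over the list alone), with Olig2 at 2.30 ± 0.45 and Nkx2-2 at 2.04 ± 0.47. The tests gave adjusted p-values of 5.14e-21 and 2.47e-12, both with adjusted p = 0.108 with an estimated correlation. Stem and progenitor genes rose for 7 of 21 and proneural genes for 8 of 24 (11 in both adjusted over the list alone), with Fabp7 at 2.07 ± 0.24 and Vim at 1.82 ± 0.27. Both had adjusted p = 1.73e-06 and adjusted p = 0.108 with an estimated correlation. RAS-MAPK output genes rose for 6 of 18 (8 adjusted over the list alone), with Spry1 at 3.06 ± 0.59, Myc at 3.00 ± 0.49, Etv4 at 2.61 ± 0.52 and Ccnd1 at 1.70 ± 0.35 (adjusted p = 1.62e-05; adjusted p = 0.158 with an estimated correlation). Microglia and macrophage genes rose for 6 of 28 (14 adjusted over the list alone), with Gpnmb at 3.21 ± 0.76 and Cd68 at 1.38 ± 0.36. Mesenchymal genes rose for 8 of 24 (11 adjusted over the list alone), with Lgals3 at 3.21 ± 0.67 and Cebpd at 2.06 ± 0.42. The adjusted p-values for these were 9.16e-10 and 5.05e-09, with adjusted p = 0.181 and adjusted p = 0.158 with an estimated correlation.

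Matrix genes rose in p53 Nf1KO gliomas for 6 of 26 (8 adjusted over the list alone), with Mmp2 at 2.91 ± 0.79 and Vcan at 2.33 ± 0.60, and chromatin genes for 4 of 15, with Hmga2 22.6-fold higher and Ezh2 at 3.24 ± 0.55. Adjusted p came to 1.24e-07 and 0.00046, with adjusted p = 0.263 and adjusted p = 0.181 with an estimated correlation. The immediate early list was called higher on 1 of 19 genes, Atf3 (2.74 ± 0.77; adjusted p = 0.026; adjusted p = 0.668 with an estimated correlation). Mature neuron genes fell for 2 of 34 (1 adjusted over the list alone; median -0.82), Dlg4 (-1.46 ± 0.33) and Grin2a (-0.76 ± 0.24), and forebrain regional genes for 1 of 25 (0 adjusted over the list alone), Lhx6 (-1.39 ± 0.44). These lists had adjusted p-values of 0.000391 and 0.0159, with adjusted p = 0.668 and adjusted p = 0.634 with an estimated correlation. Among lists not called, Eif4ebp1 rose by 1.99 ± 0.45, the p53 target Cdkn1a by 1.56 ± 0.45 and Pdgfra by 1.89 ± 0.58, while Ccng1 fell by 0.57 ± 0.16. Higher and lower members numbered 2 and 0 of 24 PI3K genes (2 and 1 adjusted over the list alone), 2 and 1 of 28 p53 targets (3 and 3 adjusted over the list alone) and 2 and 0 of 29 receptor kinases and ligands. Of 16 choroid plexus and 19 astrocyte genes 0 were called by limma. Median, mean and test differed in sign for the neuroblast, T and NK cell, endothelial, SHH pathway and choroid plexus lists.

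Models with separate controls shared many calls. Cis p53/Nf1 and p53 gliomas had 2262 higher genes in common, where independent lists would share 664.9, and 2421 lower genes, against 721.7 by chance. Of the genes called in cis p53/Nf1 gliomas, 5 higher and 1 lower were called the opposite way in p53 gliomas. Cis p53/Nf1 and p53 Nf1KO gliomas shared 789 higher genes (197.5 by chance) and 366 lower genes (106.2 by chance), with 0 opposite calls. Without p53 glioma 1 the last count of shared lower genes was 728. Among genes changed at least 2-fold, the 4 overlaps were 990, 1051, 587 and 64.

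The p53 Nf1KO and p53 gliomas, which share set Z2 and differ by the Nf1KO allele in their labels, were compared directly. Differences between the 2 models need not be effects of that allele. The homeobox genes Hoxd9 and Hoxd8 were higher in p53 Nf1KO gliomas by 5.49 ± 0.55 and 3.90 ± 0.76 (limma adjusted p = 1.63e-06 and 0.03); p53 Nf1KO glioma 3 read 6.38 for Hoxd9 and the other 3 read 9.86 to 10.82. Also higher were the collectrin gene Cltrn (1.97 ± 0.31), Polr3gl (1.76 ± 0.31), the carotenoid oxygenase Bco2 (1.65 ± 0.34), Wfdc2 (1.60 ± 0.29), Gstk1 (1.46 ± 0.30), Wdr86 (1.29 ± 0.27), the galactose mutarotase Galm (1.09 ± 0.18) and Vpreb1 (0.86 ± 0.16). In p53 Nf1KO gliomas the SD (n = 4) was 1.96 for Hoxd9, 1.80 for Hoxd8 and 1.14 for Cltrn. In p53 gliomas (n = 9) it was 0.52, 0.37 and 0.26. The standard errors and p-values use the spread shared by all groups, so they understate the spread of these genes in p53 Nf1KO gliomas. The fit to the compared groups alone called 5 genes, of which 4 were also called in the main fit. Lower were the interleukin decoy receptor Il1r2 (-1.92 ± 0.41), Ppfia1 (-1.71 ± 0.36), cyclin D1 gene Ccnd1 (-1.48 ± 0.30), cortactin gene Cttn (-1.34 ± 0.25), Nf1 and Ttc37 (-0.63 ± 0.14). Some levels were low: Ttc37 read 2.74 beside 3.37 in p53 gliomas and Vpreb1 4.39 beside 3.52. Cltrn and Hoxd8 read 2.76 and 2.94 in p53 gliomas. Lower quartiles of the Z2 arrays ran from 4.37 to 4.61, so the size of these differences may depend on values near background. Ppfia1, Ccnd1 and Cttn lie near each other on chromosome 7, as does Fadd (-2.19, limma adjusted p = 0.044), which was chosen after its value was seen. Limma called 25 genes, 13 higher and 12 lower, 20 of them at least 2-fold; 2163 had an unadjusted p under 0.05. The count was 453 without p53 glioma 1, 52, 14 and 12 without p53 Nf1KO gliomas 4, 1 and 2, 13 without Z2 forebrain 4, and 12 without any 1 of the Z1 forebrains. With quantile normalization all 3 called genes were higher, where 52.0% were in the main setting. No lower gene was called then, nor in the fit to the compared groups alone, without the lowest 40% of genes or at an adjusted p under 0.01. Of 100 groupings of these arrays, the real one included, 8 gave as many calls, so chance is not excluded for the 25.

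**Figure D3:**
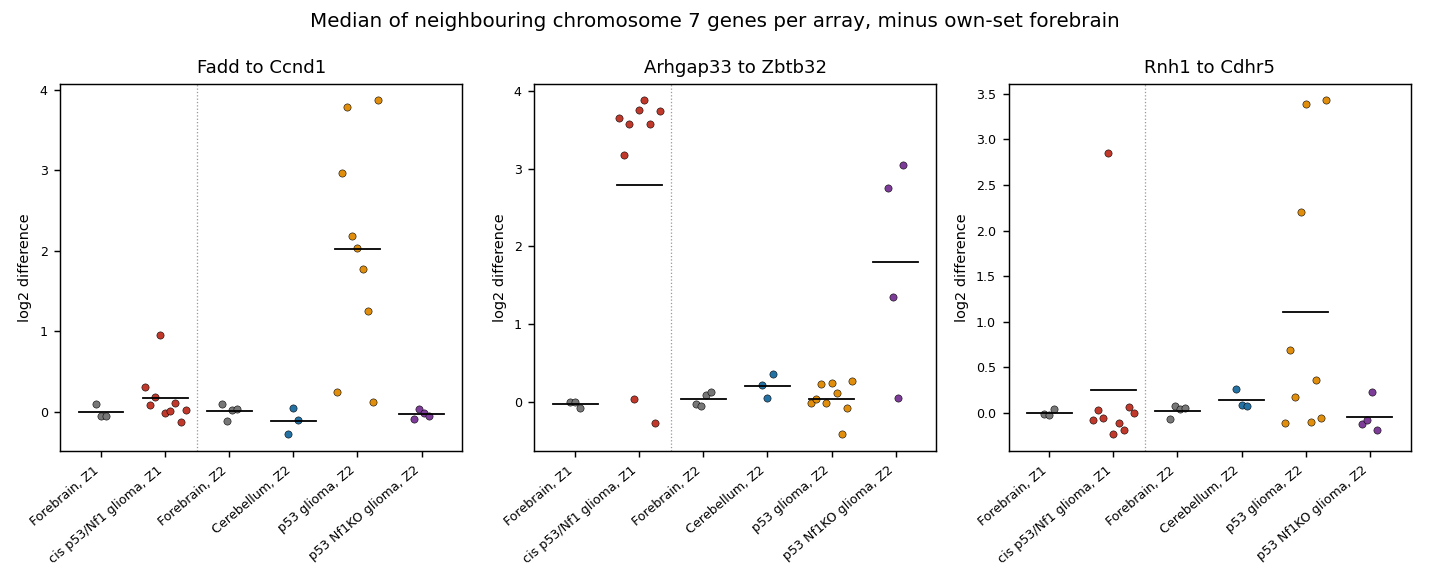
Median log2 difference from forebrain of the same set over the genes Fadd to Ccnd1, Arhgap33 to Zbtb32 and Rnh1 to Cdhr5 on chromosome 7, per array by group; points are arrays, lines are group means and the dotted line parts the sets. Fadd to Ccnd1 reads 1.25 to 3.87 in 7 p53 gliomas and -0.08 to 0.03 in the p53 Nf1KO gliomas.

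Between these models 12 lists were called with the preset correlation, none with an estimated one, and fry called 1. The choroid plexus and ependyma list was higher in p53 Nf1KO gliomas with a median of 1.57; 0 of 16 genes were called over all genes and 10 when adjusted over the list alone (adjusted p = 4.8e-12; adjusted p = 0.224 with an estimated correlation). Mature neuron (median 0.76), forebrain regional (0.47), astrocyte (0.38), immediate early (0.33) and cerebellum regional genes (0.21) were also shifted up, with 3 immediate early genes called when adjusted over the list alone. Interferon response (median -0.73, 4 of 25 called adjusted over the list alone), MHC class II (-0.57), extracellular matrix (-0.55), DNA replication (-0.43), mesenchymal (-0.36) and stem and progenitor genes (-0.33) were shifted down. Adjusted p for these 11 lists ran from 1.18e-07 to 0.0223, and each had adjusted p = 0.754 with an estimated correlation. Signs of median, mean and test differed for the PI3K, receptor tyrosine kinase, p53 target, and pericyte and fibroblast lists, which were not called.

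Cis p53/Nf1 and p53 gliomas were compared by their changes relative to own forebrain. Because each model lies in its own set, model and set cannot be told apart beyond an additive shift, and the wider spread of values in Z2 enters every value of this comparison. A positive value is a higher change in the cis p53/Nf1 model, which can be a larger rise or a smaller fall. Vim, an intermediate filament of progenitor and mesenchymal cells, was higher by this measure by 2.51 ± 0.34, and the imprinted gene Mest by 3.13 ± 0.50. The others were Tbx18 by 2.63 ± 0.65, Gkn3 by 2.48 ± 0.47, Rps6ka6 by 2.32 ± 0.54, Doc2a by 2.11 ± 0.31 and Sox3 by 1.97 ± 0.31, with Zfp867, Ankub1 and Lmcd1 between 1.77 and 1.99. For Gkn3 and Ankub1 this is a smaller fall, -0.59 and -0.48 (not called) in cis p53/Nf1 beside -3.07 and -2.46 in p53 gliomas, and Doc2a rose by 1.31 in cis p53/Nf1 and fell by 0.80 in p53 gliomas. Lower relative to the p53 model were the synaptic genes Snap25 (-3.72 ± 0.58) and Synpr (-3.84 ± 0.74), the vesicle proton pump subunit Atp6v1g2 (-3.49 ± 0.71), Serpini1 (-3.28 ± 0.66), Pcp4 (-3.12 ± 0.76) and Rgs4 (-2.89 ± 0.73). Further lower genes were the interferon-inducible Ifi204 (-3.44 ± 0.64), Slfn9 (-4.01 ± 0.64), Prm1 (-4.08 ± 0.93) and Etl4 (-3.62 ± 0.71; a second probe set read 0.07, uncalled). The Prm1 value cannot be read as a difference between models: its forebrain readings are floor values that differ between sets, 4.15 and 3.95 in Z1 beside 0.99 to 1.75 in Z2, apart from Z1 forebrain 2 at 10.01. Limma called 301 genes, 114 higher and 187 lower, 203 at least 2-fold. With quantile normalization the higher share was 55.1% in place of 37.9%. The count was 117, 84 and 102 without Z1 forebrains 1, 2 and 3, 123, 116 and 173 without Z2 forebrains 1, 3 and 4, and 472 without p53 glioma 1.

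In this comparison camera called 8 lists with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.835 with an estimated correlation), and fry called 0. Mature neuron genes lay lower in the cis p53/Nf1 model (median -2.07; 4 of 34 called, 20 adjusted over the list alone), as did astrocyte (-0.98), forebrain regional (-0.90), myelinating oligodendrocyte (-0.80) and sterol synthesis genes (-0.48; 3 adjusted over the list alone). Adjusted p was 8.74e-16 for mature neuron, 8.5e-05 for sterol synthesis and 0.000751 for the other 3, each with adjusted p = 0.835 with an estimated correlation. Microglia and macrophage (median -0.51), interferon response (-0.39) and hypoxia and glycolysis genes (-0.27) had adjusted p = 0.00776, with adjusted p = 0.888, adjusted p = 0.888 and adjusted p = 0.835 with an estimated correlation. Median, mean and test differed in sign for the p53 target, stem and progenitor, granulocyte, pericyte and fibroblast, cerebellum regional and erythrocyte lists.

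Against p53 Nf1KO gliomas, with the same limit of set and model, the change was again higher in cis p53/Nf1 gliomas for Vim (2.69 ± 0.37), Mest (2.38 ± 0.54), Sox3 (2.17 ± 0.34), Zfp867 (2.02 ± 0.35), Doc2a (1.90 ± 0.34) and Gkn3 (1.86 ± 0.50; a smaller fall, -0.59 and not called beside -2.45). It was also higher for Ccnd1 (1.88 ± 0.48), Elk3 (1.82 ± 0.46), Tcf3 (1.80 ± 0.38) and Actl6a (1.73 ± 0.46). Neuronal genes were lower: Kalrn by -5.45 ± 1.19, Hpcal4 by -5.28 ± 1.48, Elmod1 by -5.23 ± 1.21, Vsnl1 by -4.98 ± 1.12, Nefl by -4.91 ± 1.17, Gria1 by -4.88 ± 1.20, Cck by -4.85 ± 1.10, Sphkap by -4.77 ± 0.96, Nrsn1 by -4.76 ± 0.98 and Ddn by -4.61 ± 1.09. The other Kalrn probe sets read -1.15 and -1.10, uncalled. Nf1 itself differed by 0.72 ± 0.25 and was not called (limma adjusted p = 0.101). Limma called 680 genes, 278 higher and 402 lower, 471 at least 2-fold, and the higher share was 54.5% with quantile normalization in place of 40.9%. The count was 309, 270 and 303 without Z1 forebrains 1, 2 and 3, 369 and 390 without Z2 forebrains 1 and 3, 251 and 1142 without p53 Nf1KO gliomas 2 and 4, and 1128 without p53 glioma 1.

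Here camera called 10 lists with the preset correlation and 0 with an estimated one, and fry called 1. Mature neuron genes had a median of -2.83, with 11 of 34 called and 29 adjusted over the list alone (adjusted p = 2.03e-22; adjusted p = 0.606 with an estimated correlation). Lower medians were also found for forebrain regional (-1.37), astrocyte (-1.12), myelinating oligodendrocyte (-1.04), choroid plexus (-0.91), immediate early (-0.89) and sterol synthesis genes (-0.29). Higher ones were found for oligodendrocyte progenitor (0.89) and stem and progenitor genes (0.48). These 8 lists had adjusted p from 2.75e-05 to 0.0365 and adjusted p = 0.733 with an estimated correlation in each. DNA replication genes had a median of 0.91, with 6 of 29 called adjusted over the list alone (adjusted p = 0.00137; adjusted p = 0.78 with an estimated correlation). Signs of median, mean and test differed for the T and NK cell and the erythrocyte lists.

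Cerebellum and forebrain of set Z2 were compared as the normal tissues. Granule and Purkinje cell genes were high in cerebellum: the granule cell GABA receptor subunit Gabra6 256-fold (11.23 ± 1.44, SD, n = 3, beside 3.23 ± 0.25, SD, n = 4), the Purkinje cell gene Pcp2 by 7.72 ± 0.32 and the granule cell gene Cbln3 by 7.21 ± 0.30. Crtam (6.41 ± 0.45), Sycp1 (5.34 ± 0.38), the D-amino acid oxidase Dao (5.12 ± 0.27), Ppp1r17, Nrk, Skor1 and Aqp6 followed. Transcription factors of the telencephalon were low, among them Fezf2 (-6.01 ± 0.92), Tbr1 (-5.96 ± 1.04) and Dlx2 (-5.78 ± 0.62), with Lhx2 at -4.99, Emx2 at -4.90, and Crym, Gda, Ddn and Ankrd63 between -5.39 and -4.92. Of 27 cerebellum regional genes 16 were higher (19 adjusted over the list alone) and 1, Nectin3 (-1.54 ± 0.36), lower (adjusted p = 3.77e-29; adjusted p = 0.000308 with an estimated correlation). Forebrain regional genes were lower for 13 of 25, 18 adjusted over the list alone (adjusted p = 2.64e-23; adjusted p = 0.00503 with an estimated correlation). Neuroblast genes were lower for 5 of 15 (6 adjusted over the list alone), with Dlx5 at -3.57 ± 0.63, against 1 higher, Nrep (1.04 ± 0.25; adjusted p = 6.34e-07; adjusted p = 0.00247 with an estimated correlation). The SHH pathway list was not called by camera but was called higher by fry (fry adjusted p = 0.0424). In it 2 of 17 genes were higher, Gli1 (2.00 ± 0.24) and Boc (1.56 ± 0.43). When adjusted over the list alone 1 was lower, Ccnd2 (-2.28 ± 0.71, limma adjusted p over all genes 0.0572).

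Of 8 lists called between the tissues, the 3 above were also called with an estimated correlation, and fry called 4. The other 5 shifted less. Microglia and macrophage (median -0.56), immediate early (-0.37, with Egr2 at -4.38 ± 0.76), proneural (-0.26), sterol synthesis (-0.24) and mature neuron genes (-0.24, 3 of 34 called and 5 adjusted over the list alone, with Nrgn at -3.83 ± 1.04) were shifted down, with adjusted p from 1.24e-05 to 0.00773. With an estimated correlation they had adjusted p = 0.774, adjusted p = 0.869, adjusted p = 0.774, adjusted p = 0.869 and adjusted p = 0.931 with an estimated correlation. The stem cell gene Nr2e1 was lower by -3.87 ± 0.42. Limma called 886 genes between the tissues, 475 higher and 411 lower in cerebellum, 623 at least 2-fold. The majority depended on the setting. Higher and lower genes numbered 381 and 447 with median-centring and 284 and 345 in the fit to the compared groups alone. They numbered 191 and 247 without the lowest 40% of genes, but 323 and 311 with quantile normalization. The count was 300, 1482 and 265 without cerebella 1, 2 and 4, and 574, 555 and 589 without forebrains 1, 2 and 4. Cerebella 1 and 4 differed by 0.368 (root mean square, log2) and cerebellum 2 differed from them by 0.737 and 0.739. Median, mean and test differed in sign for the PI3K, p53 target, mitosis, pericyte and fibroblast, and hypoxia lists.

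Forebrain of Z1 against forebrain of Z2, the same tissue in both sets, had 14366 genes called by limma, 13919 of them higher in Z1, with a median difference of 1.79 over all genes. The median was 0.02 and the higher share 53.1% with quantile normalization, where 9183 genes were still called, and 0.22 and 61.0% with median-centring, beside 96.9% in the main setting. Values are therefore set side by side only within a set or as differences from own forebrain.

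Whole chromosomes were tested because Trp53 and Nf1 both lie on chromosome 11. No shift of chromosome 11 was called in any of the 5 contrasts. Chromosome 19, with 555 genes, was shifted down in cis p53/Nf1 gliomas (median -0.14, adjusted p = 0.00424; adjusted p = 0.943 with an estimated correlation). It was also shifted down relative to p53 gliomas (median -0.21, adjusted p = 6.19e-07; adjusted p = 0.977 with an estimated correlation) and to p53 Nf1KO gliomas (median -0.09, adjusted p = 0.00343; adjusted p = 0.995 with an estimated correlation). No chromosome was called in the p53 or the p53 Nf1KO gliomas against forebrain.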

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

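Of the tests of explanations below, the regroupings of samples and the test of spermatid genes were written before the results were seen; the others, and the runs without p53 glioma 1, were chosen after.

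The p53 glioma 1 array lay near normal forebrain: it had covered 14.2% of the mean change of its group, where the other p53 gliomas had covered 74.6% to 140%, and it read 0.74 for the mitosis list where the next lowest read 3.19. Whether it is mostly normal tissue with a small share of tumour stays open: the tumour share was 3.26% from higher genes and 12.96% from lower genes, 9.70 percentage points apart, but an array picked for lying near forebrain gives small shares in any case. A label exchanged with a forebrain array was left undecided by the share of tumour-high genes that lay above all 4 forebrains (40.3% beside a bound of 40, with 20.6% to 31.4% in the forebrains themselves and an SD of 4.64). Exchange with any of the 4 Z2 forebrains is argued against by Prm1, which read 8.22 above the highest of them. The mitosis list argues against exchange with a forebrain of either set, which would leave a tumour under a forebrain label. The list ran from -0.18 to 0.27 in the Z2 forebrains and from -0.04 to 0.07 in the Z1 forebrains, each relative to their mean. Without p53 glioma 1 limma called 453 genes between p53 Nf1KO and p53 gliomas in place of 25.

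Between p53 Nf1KO and p53 gliomas, neuronal, astrocyte and choroid plexus lists shifted up and replication, interferon and mesenchymal lists down. With an estimated correlation none of these shifts is called (adjusted p = 0.224 for choroid plexus and 0.754 for each of the others), and limma called 0 of their members over all genes. A larger share of normal brain in the p53 Nf1KO samples may account for part of this, because across genes the difference had a slope of -0.187 on the tumour change of the cis p53/Nf1 model (-0.102 without p53 Nf1KO glioma 2 to -0.270 without p53 Nf1KO glioma 4). The choroid plexus and ependyma list shifted more than that slope predicts: its mean of 1.74 exceeded the predicted 0.203 by 1.54. The prediction rests on the list's change in the cis p53/Nf1 model, and the list varied widely within groups. Relative to the forebrain mean it ran from -1.48 to 0.97 in p53 Nf1KO gliomas (n = 4). It ran from -2.34 to -0.82 in p53 gliomas (n = 9) and from -1.37 to 0.79 in Z2 forebrains (n = 4). Whether a share of normal brain accounts for this list therefore stays open. Differences in where the samples were taken, with more ventricle lining in some, could also raise that list and were not tested.

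The chromosome 7 stretch Fadd, Ano1, Fgf3, Fgf4 and Fgf15, picked from the data, had a median of -1.83 between p53 Nf1KO and p53 gliomas, but limma called only Fadd (adjusted p = 0.044; the other 4 had 0.283, 0.44, 0.137 and 0.33). Chance order of genes gave a stretch as low in 0 of 1000 shuffled orders, though narrowly, the lowest shuffled median being -1.80. Whether a smaller tumour share in p53 Nf1KO samples could give this stays open: the stretch kept -4.01% of its p53 glioma change beside 74.6% for other genes (percentile 0.481 of 1456), but its genes were chosen for that difference, so this decides nothing. DNA was not measured. In single gliomas a stretch of 7 neighbours rose above the highest of 100 shuffled orders in 17 of 22, and in 0 of 7 forebrains but 2 of 3 cerebella. Several of these stretches hold members of a gene family, such as Hoxa, Slfn or Ccl genes, and those of cerebellum 2 hold Hoxa and Hoxb genes. Their number cannot be read as a number of DNA gains. Each forebrain was set against the other forebrains of its set, but gliomas and cerebella against forebrain. The 0 of 7 is therefore not a like comparison.

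Regrouping the samples at random tests whether chance can be excluded. It can for the numbers of genes in most comparisons, where the real grouping was the 1 with the largest count: 7266 in cis p53/Nf1 gliomas (highest other 1399; 1 of 100), 6599 in p53 gliomas (6058; 1 of 100) and 1427 in p53 Nf1KO gliomas (33; 1 of 35). So it can for 886 in cerebellum (398; 1 of 35) and 14366 between forebrain sets (12715; 1 of 35). In the comparisons relative to own forebrain the real grouping also had the largest counts, 301 and 680 (0 and 15; 1 of 100 each). There the other groupings mix the sets and only the real one follows the set and its shared forebrains, so chance differences in the forebrains, or a difference between sets, are not excluded. It cannot for the 25 genes between p53 Nf1KO and p53 gliomas, where 8 of 100 groupings gave as many and the highest gave 2748. What the arrays of that grouping have in common was not tested. Chance cannot be excluded for any number of gene lists: 16 in cis p53/Nf1 gliomas (13 of 100 groupings; highest other 19), 16 in p53 (38 of 100; 21), 14 in p53 Nf1KO (15 of 35; 23), 12 between the Z2 models (41 of 100; 17), 8 and 10 relative to own forebrain (66 and 41 of 100; 17 in both) and 8 in cerebellum (17 of 35; 12). Nor can it for chromosomes, with 1 in cis p53/Nf1 gliomas (90 of 100, highest other 12). In p53 and p53 Nf1KO gliomas 0 chromosomes were called, so every grouping gives as many (100 of 100 and 35 of 35) and nothing is tested. The highest other counts there were 9 and 3. Relative to own forebrain 1 and 1 were called (98 and 100 of 100, 11 in both). In the 3 models the other groupings called a median of 12, 14 and 12 lists but of 0 genes. The preset correlation thus gives many list calls under other groupings too, so the number of lists cannot decide this. Single lists were not tested in this way.

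Arrays apart from their group were sought with Dixon's test of the gap to the nearest array over the range, which marks about 1 in 20 groups by chance; it marked 17 of 128 groups for list means and 54 of 420 for genes, 23 of these in p53 glioma 1 and 11 in Z2 forebrain. For list means (gap over range in brackets): P53 glioma 9 was highest for targeted and mTOR complex genes (0.516). P53 Nf1KO glioma 1 was lowest for targeted and mTOR complex genes (0.834). The highest value belonged to cis p53/Nf1 glioma 5 for PI3K-AKT-mTOR signalling (0.610), and it was lowest for DNA replication (0.560). Highest in its group was cis p53/Nf1 glioma 4 for receptor tyrosine kinases and ligands (0.539). P53 glioma 1 was lowest for mitosis (0.593), DNA replication (0.538), oligodendrocyte progenitor (0.528), neural stem and progenitor (0.569), interferon response (0.632), mesenchymal glioma (0.518) and highest for neuroblast and immature neuron (0.649). The lowest value belonged to cis p53/Nf1 glioma 8 for oligodendrocyte progenitor (0.640), proneural glioma (0.571). P53 Nf1KO glioma 2 was lowest for oligodendrocyte progenitor (0.848). P53 Nf1KO glioma 3 was highest for SHH pathway (0.832). P53 glioma 7 was highest for erythrocyte (0.498).

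For genes, again with the gap over the range: Z2 forebrain 3 was highest for Ankub1 (0.856), Cbln3 (0.959), Mcm6 (0.837) and lowest for Nr2e1 (0.834), Snap25 (0.897). P53 glioma 1 was lowest for Ccnb1 (0.654), Cdk1 (0.707), Cxcl10 (0.641), Ect2 (0.699), Esco2 (0.562), Ifi204 (0.565), Lcn2 (0.518), Mx1 (0.527), Myc (0.641), Nkx2-2 (0.761), Nusap1 (0.615), Oasl2 (0.633), Olig2 (0.524), Pbk (0.648), Pclaf (0.524), Pole (0.592), Prm1 (0.593), Slfn9 (0.499), Tk1 (0.611), Usp18 (0.732), Vcan (0.518), Vim (0.751) and highest for Dlg4 (0.649). The highest value belonged to cis p53/Nf1 glioma 8 for Deptor (0.524), and it was lowest for Mtor (0.731), Nxf3 (0.595), Pdgfra (0.648), Rab33a (0.5261), Vcan (0.535). Highest in its group was cis p53/Nf1 glioma 4 for Doc2a (0.722), and it was lowest for Olig2 (0.524). The highest value belonged to cis p53/Nf1 glioma 6 for Fabp7 (0.555). P53 Nf1KO glioma 4 was highest for Gpnmb (0.906) and lowest for Wfdc2 (0.831). P53 glioma 8 was lowest for Gstk1 (0.624). P53 glioma 9 was highest for Hoxd8 (0.700). The lowest value belonged to cis p53/Nf1 glioma 5 for Mcm4 (0.513), Rrm2 (0.616), and it was highest for Pdpk1 (0.734). Highest in its group was cis p53/Nf1 glioma 3 for Mog (0.645). Z2 forebrain 4 was highest for Nectin3 (0.841), S100a4 (0.832). Z2 forebrain 2 was highest for Pclaf (0.955), Vsnl1 (0.891). P53 glioma 6 was highest for Polr3gl (0.563). The highest value belonged to cis p53/Nf1 glioma 7 for Rgs4 (0.550), and it was lowest for Slfn9 (0.514). Z2 forebrain 1 was highest for Tbx18 (0.851) and lowest for Them6 (0.830).

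Genes called between models numbered 25, 301 and 680, with the limits that the regroupings above set to each number. Between p53 Nf1KO and p53 gliomas they include Hoxd9 (5.49), Hoxd8 (3.90), Cltrn (1.97), Polr3gl (1.76), Bco2 (1.65), Wfdc2 (1.60), Gstk1 (1.46), Wdr86 (1.29), Galm (1.09), Vpreb1 (0.86), Il1r2 (-1.92), Ppfia1 (-1.71), Ccnd1 (-1.48), Cttn (-1.34), Nf1 (-0.78) and Ttc37 (-0.63). Cis p53/Nf1 against p53 gliomas, relative to own forebrain, include Mest (3.13), Tbx18 (2.63), Vim (2.51), Gkn3 (2.48), Rps6ka6 (2.32), Doc2a (2.11), Zfp867 (1.99), Ankub1 (1.98), Sox3 (1.97), Lmcd1 (1.77), Prm1 (-4.08, from floor values), Slfn9 (-4.01), Synpr (-3.84), Snap25 (-3.72), Etl4 (-3.62), Atp6v1g2 (-3.49), Ifi204 (-3.44), Serpini1 (-3.28), Pcp4 (-3.12) and Rgs4 (-2.89). Against p53 Nf1KO gliomas they include Vim (2.69), Mest (2.38), Sox3 (2.17), Zfp867 (2.02), Doc2a (1.90), Ccnd1 (1.88), Gkn3 (1.86), Elk3 (1.82), Tcf3 (1.80), Actl6a (1.73), Kalrn (-5.45), Hpcal4 (-5.28), Elmod1 (-5.23), Vsnl1 (-4.98), Nefl (-4.91), Gria1 (-4.88), Cck (-4.85), Sphkap (-4.77), Nrsn1 (-4.76) and Ddn (-4.61).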

How the results depend on the processing

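The runs without p53 glioma 1 and without cis p53/Nf1 gliomas 4 and 8 were chosen only after the results were seen, and the number of arrays limits the precision of all values. Over the alternatives run, 287 results for named genes gave 7606 values, of which 7197 were the same, 394 weaker, 8 stronger and 7 reversed. A result counted as the same also when it was called in neither fit. Arrays were left out for every contrast, also those that do not hold the array. Many of these values could therefore hardly change, and the totals do not measure how robust any 1 comparison is. For lists, 224 gene list results gave 1120 values, with 974 the same, 119 weaker, 27 stronger and 0 reversed; 97 of 100 chromosome values were the same and 3 weaker. The second deposited table is identical in every cell and so gave no separate values. With the probe set of largest variance the sign reversed for Mtor (0.15 in cis p53/Nf1 and 0.46 in p53 gliomas) and Etl4 (0.068). Without the lowest 40% of genes the p53 Nf1KO against p53 comparison had 1 gene, cerebellum 438 and the forebrain sets 7983. Quantile normalization gave 3 genes for p53 Nf1KO against p53, 1094 and 2055 for cis p53/Nf1 against p53 and against p53 Nf1KO, and 9183 between forebrain sets. Array weights gave 2999 genes in p53 Nf1KO gliomas, 77 against p53 gliomas, 2528 and 2771 for the cis p53/Nf1 comparisons and 4808 in cerebellum; the cause was not tested. A fit to the compared groups alone gave 5 genes for p53 Nf1KO against p53 and 1507 for cis p53/Nf1 against p53 Nf1KO. The replicate block gave 4 (all higher, Nf1 at -0.77 not among them) and 332 there; replicate numbers do not pair arrays, since 21 correlations between arrays of the same number ran from -0.33 to 0.45 with 5 over 0.1. An added 2-fold threshold left 3828, 2865 and 807 genes in cis p53/Nf1, p53 and p53 Nf1KO gliomas, and overlaps of 990 higher and 1051 lower (cis p53/Nf1 and p53) and 64 lower (cis p53/Nf1 and p53 Nf1KO). An adjusted p under 0.01 left 4078 in p53, 393 in p53 Nf1KO, 2 between these, 61 and 134 in the cis p53/Nf1 comparisons and 389 in cerebellum. All 7 forebrains as 1 group gave 13634, 11840 and 9499 genes in the 3 models and 1582 in cerebellum, and reversed Ccng1 (0.038), P2ry13 (0.13) and Trp53 (0.91) in cis p53/Nf1 and Nf1 (-0.60) in p53 gliomas. Cerebellum as the reference gave 2934 in p53 Nf1KO gliomas, and a direct difference without forebrain 15371 and 14881 in the cis p53/Nf1 comparisons. Without cis p53/Nf1 gliomas 4 and 8 the counts were 46 for p53 Nf1KO against p53 and 465 for cis p53/Nf1 against p53. Camera with an estimated correlation called 0 lists in cis p53/Nf1, 0 in p53, 0 in p53 Nf1KO, 0 between these, 0 and 0 in the cis p53/Nf1 comparisons and 3 in cerebellum, and 0, 0 and 0 chromosomes in the 3 contrasts that had 1. Fry called 1 list for p53 Nf1KO against p53, 0 and 1 in the cis p53/Nf1 comparisons and 4 in cerebellum.

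With single arrays left out, gene counts ranged over 5938 to 7454 in cis p53/Nf1, 5369 to 7574 in p53 and 412 (without p53 Nf1KO glioma 4) to 2503 (without p53 Nf1KO glioma 2) in p53 Nf1KO gliomas. They ranged over 12 (without Z1 forebrain 1) to 453 (without p53 glioma 1) between the latter, 84 (without Z1 forebrain 2) to 472 (without p53 glioma 1) and 251 (without p53 Nf1KO glioma 2) to 1142 (without p53 Nf1KO glioma 4) in the cis p53/Nf1 comparisons. The range was 265 (without cerebellum 4) to 1482 (without cerebellum 2) in cerebellum and 13771 to 14514 between forebrain sets. Without p53 glioma 1 the lists called numbered 16, 16, 14, 16, 10, 11 and 8 in the same order, and the overlaps were 2622 higher and 2723 lower (cis p53/Nf1 and p53) and 1116 higher and 728 lower (cis p53/Nf1 and p53 Nf1KO).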

Other observations

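The genes and arrays described here were picked only after their values were seen, while the test of spermatid genes was written before its result. The stretch Rnh1 to Cdhr5 on chromosome 7, which holds the oncogene Hras, was 2.85 above forebrain in cis p53/Nf1 glioma 4 and 2.20, 3.39 and 3.43 in p53 gliomas 4, 5 and 9; 7 neighbours in it passed the highest of 100 shuffled gene orders only in p53 gliomas 5 and 9. The stretch Arhgap33 to Zbtb32 read 2.75, 1.34 and 3.05 in p53 Nf1KO gliomas 1, 2 and 4, below the highest shuffled stretch of each array (3.28, 2.10 and 3.31), and lay near forebrain in cis p53/Nf1 gliomas 4 and 8 (0.03 and -0.27) and in all p53 gliomas (-0.42 to 0.26).

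Prm1 read 10.53 to 11.36 in the Z2 gliomas apart from p53 glioma 1 (9.98), and 0.99 to 1.83, at or next to the lowest value of each array, in the 7 Z2 controls. Expression of spermatid genes in general is argued against: of 15 pairs of the genes Prm2, Tnp1, Tnp2, Smcp and Odf1 with a glioma model, 0 were called higher by limma, with differences from -0.23 to 0.12. A hypothesis is that the signal could come from protamine 1 sequence carried by the cre transgene, which all 3 models share by their labels; the sources used here do not describe that construct and this was not tested. It would be decided by the construct's sequence set against the Prm1 probes, and by genotyping Z1 forebrain 2 (10.01) for cre, neither of which is available here.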
